A study of Drosophila melanogaster with 10 samples.

How the data were processed

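Total RNA of whole testes was profiled, per the labels, after ribosomal RNA depletion and with a stranded library kit, in 5 conditions of 2 libraries each. The deposited files give raw read counts per gene, as whole numbers, for 17412 FlyBase gene identifiers, with no normalization by the authors that the values show. Per the submitters' processing notes, Trim Galore 0.4.1, STAR 2.5.1b and the dm6 genome were used. The read counter, its strand setting, the treatment of reads that map to several places and the gene annotation are not given in the sources used here. Values of genes that overlap another gene or have an antisense partner are uncertain, as are those of near-identical neighbours such as scpr-A, scpr-B and scpr-C, the GstD genes, the S-Lap genes and the Mst57D and Mst84D genes, among which reads could be split or lost. Groups and replicate numbers were taken from the labels. Symbols, gene types and coordinates came from Ensembl release 115 of the same assembly, in which 17138 identifiers had a symbol and 274 did not.

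Library totals were 18139629 and 20226197 counts in WT, 24138347 and 26851858 in B9d1 KD, 27711393 and 30798942 in the libraries labelled Tektin-C KD, 24690735 and 27500068 in those labelled Klp59D KD, and 17621525 and 19807188 in the sa mutant. The 2 libraries of each group were compared before anything else was computed. Their depth ratio was 1.11 to 1.12 in all 5 groups, and 5.85% to 6.07% of genes with 50 to 5000 counts lay outside their 95% binomial range. The biological coefficient of variation was 0.0166 within pairs and 0.603 between the 3 genotypes labelled mature spermatocyte. Beyond a replicate number, nothing in the labels says that the 2 libraries came from separate flies. They were counted as technical repeats, their counts were summed, and every group became 1 sample. The planned tests (edgeR quasi-likelihood tests, camera gene set tests and adjusted p-values) measure only the spread between such libraries and were set aside. Their order of genes served only to choose the named genes, and their counts are given with the alternatives. Libraries with the same number deviated together. The log2 ratio of library 2 to library 1, relative to the group's median ratio, correlated at 0.103 to 0.188 over 6231 genes in every pair of groups. The numbers therefore pair the libraries, as this check of the data and not the labels shows.

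Genes passing edgeR's filterByExpr were kept (13831). The summed counts were scaled by TMM factors (0.756 in WT, 1.13 in B9d1 KD, 0.815 and 1.11 in the libraries labelled Tektin-C KD and Klp59D KD, 1.29 in the sa mutant), and log2 scaled counts per 1e6 (CPM) were computed from the deposited counts with a prior count of 2. The log2 fold is the difference between samples, or between a sample and the mean of 2 samples on the log2 scale. The main value of a comparison is the number of genes at least 2-fold apart. A count of 0 was given the upper limit of 3 counts, which is 0.103 CPM in WT, 0.0519 in B9d1 KD, 0.0629 and 0.0520 in the libraries labelled Tektin-C KD and Klp59D KD, and 0.0620 in the sa mutant. Fold intervals are exact binomial (Clopper-Pearson) at the 95% level, and without molecular identifiers they and the floors cover counting error only. They are not given against the mean of 2 samples. Fitted folds of genes with 0 counts depend on the prior count. Setting such members to their bound left the list medians in the report the same to 2 decimals.

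Before the data were examined, 33 gene lists of 566 named members, the comparisons, the alternatives and the rule for named genes were fixed; 48 members matched no identifier. Lists with fewer than 5 measured members were given no percentile. Percentiles came from 10000 random lists matched over 20 bins of mean expression. The rule named, per comparison, the 4 targeted genes, the 5 largest differences in each direction, and from each described list up to 4 measured members with the smallest p. The largest differences were taken among genes with an adjusted p under 0.05, an average log2 CPM of at least 4, no overlap of CPM between the libraries compared, and a symbol that is not a CG, CR, asRNA or lncRNA number or a structural or mitochondrial RNA. The sa-dependent genes were to pass an adjusted p as well as a log2 fold of -2 or below; only the fold was used, because no test was made.

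Alternatives were RLE factors, library size alone, no low-count filter (16513 genes), CPM over 5 in at least 2 libraries (10563 genes), leaving out 638 structural RNA and mitochondrial genes, leaving out each library, only the compared libraries in the fit, a replicate block, DESeq2, and the mean of 3 references. Each reference alone, the stage fit (with each genotype in turn as its single sample) and the sums in place of tests were chosen after seeing the data. Each alternative's list percentiles used 1000 random lists. The steps were tested on simulated counts of 13831 genes. For B9d1 KD against WT, 100% of genes changed 4-fold, 8-fold or 16-fold and 50% of those changed exactly 2-fold were at least 2-fold apart, as were 0.345% of unchanged genes. This simulation held counting noise only, with 50 genes changed by each fold and 13631 unchanged. In the data 7333 genes were at least 2-fold apart. It therefore cannot show how well the scaling recovers folds when most genes differ. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.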

Results

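Gene-level RNA counts were measured in whole testes of Drosophila melanogaster under 5 conditions, with 2 deposited libraries per condition. Wild-type (WT) testes hold every male germ cell stage. B9d1 KD, Tektin-C KD and Klp59D KD are RNA interference knockdowns driven in the germ line by bam-Gal4, a driver active in the late dividing spermatogonia, together with extra Dicer-2. The sa mutant lacks a testis-specific TATA-binding-protein-associated factor (TAF) that spermatocytes need to switch on the meiotic and spermatid programs. Per the labels, B9d1 KD testes were enriched for young spermatocytes and the other 3 altered genotypes for mature spermatocytes. Each library came from 100 pairs of testes of males under 2 days old. WT grew at 22°C for 10 days, the sa mutant at 22°C for 12 days, and the knockdowns at 22°C for 3 days and then 30°C for 8 days, so temperature separates the knockdowns from the other two conditions.

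The 10 libraries held 17621525 to 30798942 counts each. The 2 libraries of every condition differed by little more than the sampling noise and were summed and counted as 1 sample. Within pairs, the median squared deviation of genes with 50 to 5000 counts was 1.03 to 1.08 times the binomial expectation, against 27.7 to 281 times between conditions. For genes with 5000 counts or more it was 1.32 to 1.55 times the expectation within pairs. No comparison has a replicate check, no p-value is given for any of them, and a difference below is a difference between these samples. The summed samples held 29006081 effective counts (after scaling) in WT, 57842387 in B9d1 KD, 47663574 and 57694802 in the libraries labelled Tektin-C KD and Klp59D KD, and 48412787 in the sa mutant. Intervals in square brackets are exact 95% intervals of a fold and cover counting error only. A gene list is described by its median log2 fold and that median's percentile among 10000 random lists of the same size matched on expression. With library size alone in place of the scaled totals, the median log2 fold of all genes moved from 0.08 to 0.65 in B9d1 KD against WT, from 0.13 to 0.23 in the library labelled Tektin-C KD, from 0.05 to 0.59 in that labelled Klp59D KD and from 0.02 to 0.78 in the sa mutant. It moved from -0.04 to 0.22 in B9d1 KD against the other two knockdowns, from -0.04 to -0.47 between those 2, and from 0.05 to -0.14 in B9d1 KD against the sa mutant. All values below are relative to the scaled totals.

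The targeted transcripts were examined first, because they check the labels. B9d1 (FBgn0038342; dm6 3R, 15481906 to 15482904, plus strand) encodes a protein of the ciliary transition zone, the gate at the base of the cilium. Its level was 8.91 and 9.92 scaled counts per 1e6 (CPM) in the 2 B9d1 KD libraries and 108 to 195 CPM in all others, and it was 11.5-fold lower than in WT (fold 0.0871 [0.0791 to 0.0950]). The sa transcript (3L, 21405425 to 21406738, minus strand) stood at 3.73 and 3.24 CPM in the sa mutant, 11.2-fold below WT (fold 0.0896 [0.0749 to 0.104]), and at 36.7 to 169 CPM elsewhere. Tektin-C (3L, 5794405 to 5796543, minus strand), which encodes a filament protein of axonemal microtubules, and Klp59D (2R, 23141999 to 23144497, plus strand), which encodes a microtubule-depolymerizing kinesin, went against their labels. Tektin-C was at 201 and 204 CPM in the libraries labelled Tektin-C KD, near the 217 and 225 CPM of WT, and at 12.7 and 11.6 CPM in those labelled Klp59D KD. Klp59D was at 333 and 336 CPM in the libraries labelled Klp59D KD and at 29.3 and 30.0 CPM in those labelled Tektin-C KD, against 340.3 CPM in the summed WT sample. Each low transcript was also the lowest of the 5 conditions, by 6.60-fold for Klp59D and 4.96-fold for Tektin-C. These 2 knockdowns are therefore called "the library labelled Tektin-C KD" and "the library labelled Klp59D KD" throughout, and every direction given for them follows the label and not the transcript.

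**Figure D1:**
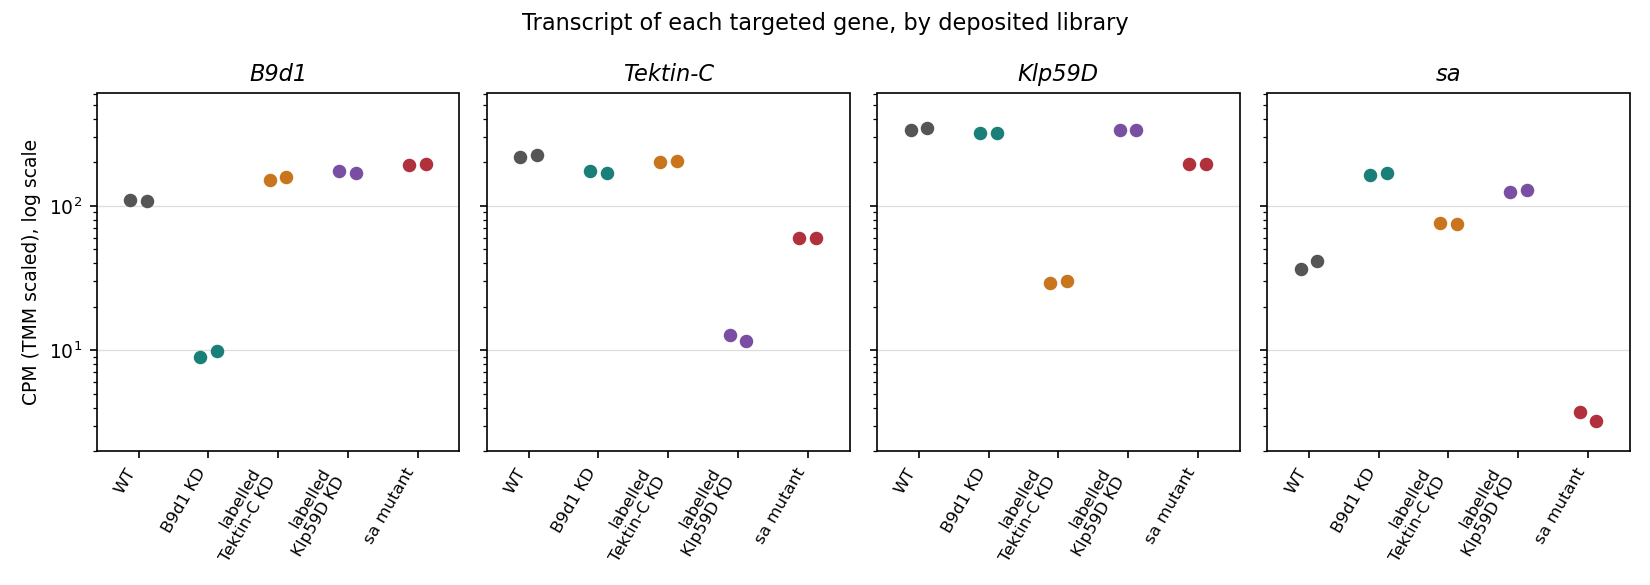
Level of each targeted transcript in CPM (TMM scaled, log axis) in every deposited library, 1 point per library and 2 per condition. B9d1 and sa are lowest under their own labels, at 8.91 to 9.92 and 3.24 to 3.73 CPM, whereas Tektin-C is lowest in the libraries labelled Klp59D KD (11.6 to 12.7 CPM) and Klp59D in those labelled Tektin-C KD (29.3 to 30.0 CPM).

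B9d1 KD testes were compared with WT to describe how their transcripts differ. Knockdown, driver, extra Dicer-2, temperature and mix of germ cell stages all differ between them, so these cannot be told apart. The same holds for the other two knockdowns against WT. Most measured members of the early germ line and tMAC lists were at least 2-fold higher, 16 of 29 spermatid differentiation genes were lower, and other late lists were mixed. All 8 subunits of tMAC, the testis chromatin complex that activates spermatocyte genes, were measured, and 7 were at least 2-fold higher (median 1.86, percentile 99.96). Among them comr was at 84.7 against 6.96 CPM (12.1-fold, [10.6 to 14.1]) and aly at 116 against 28.0 CPM. Of 18 germline stem cell and spermatogonial genes, 12 were at least 2-fold higher and none lower (median 1.68, percentile 99.99), including the translational repressor nanos at 50.2 against 8.07 CPM and the piRNA helicase spn-E at 123 against 25.1 CPM. The testis TAFs (3 of 5 higher, median 1.58) included can at 108 against 18.0 CPM.

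Cell cycle and DNA replication genes were higher in 15 of 25 cases and lower in none (median 1.49, percentile 99.99), with the spindle checkpoint kinase BubR1 at 201 against 26.4 CPM and the ribonucleotide reductase subunit RnrS at 71.0 against 5.45 CPM. Male meiotic chromosome genes were higher in 6 of 10 (median 1.45), with SA2 9.69-fold higher. Spermatocyte regulators were higher in 8 of 14 and lower in 1 (median 1.21), including Rbp4 at 294 against 67.0 CPM. The ciliary groups were also higher in part: 4 of 7 measured transition zone genes (median 1.48), where the 1 lower gene was B9d1 itself, and 7 of 15 centriole and basal body genes (median 0.90, percentile 98.1).

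Spermatid differentiation genes were lower in 16 of 29 cases and higher in 1 (median -1.09, percentile 0.055). The sperm tail gene Mst84Db was at 448 against 8374 CPM (18.7-fold lower), Mst87F at 412 against 3225 CPM, and the sperm leucyl aminopeptidase gene S-Lap1 at 2306 against 8557 CPM. The cup and comet genes, which are transcribed after meiosis, had a median of -0.83 (percentile 2.27; 6 of 15 lower, none higher), with w-cup at 506 against 2772 CPM. Y-linked fertility genes split, with 5 of 12 lower and 2 higher (median -0.74, percentile 5.48). ORY was 11.4-fold lower and the axonemal dynein gene kl-5 2.06-fold lower, while FDY was 3.70-fold higher. Axoneme genes had a median near that of all genes (0.04), although the testis tubulin gene betaTub85D was at 1150 against 3726 CPM.

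For the protein synthesis machinery, the result depended on the class. Ribosome biogenesis genes were at least 2-fold higher in 38 of 71 cases and lower in 2 (median 1.06, above all 10000 random lists). Nlp, a nucleoplasmin-like histone chaperone, was at 197 against 55.9 CPM. The list includes Rrp1 (5.47-fold higher), a symbol that in flies names a DNA repair nuclease. The 71 cytosolic ribosomal protein genes had a median of -0.17 (percentile 65.1; 3 lower, none higher), which became 0.41 with library size alone. Small nucleolar RNAs (snoRNAs), the guides of ribosomal RNA modification, were at least 2-fold lower in 145 of 210 cases and higher in 7 (median -1.47, below all random lists). snoRNA:Psi28S-3342 was at 845 against 3047 CPM.

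Markers of other tissues differed at the same time. All 22 accessory gland markers were measured, and 19 were at least 2-fold higher (median 4.30), with the seminal fluid gene Acp36DE at 347 against 14.4 CPM. Of 15 muscle sheath markers, 13 were lower (median -2.33), with the myosin gene Mhc at 130 against 673 CPM. Ejaculatory duct and bulb markers had a median of -1.81 over 6 genes. The mitochondrial genome gave 1.75% and 1.76% of counts in the B9d1 KD libraries and 7.47% and 7.51% in WT. Extremes were named only among genes allowed by the naming rule. It requires, among other limits, an average log2 CPM of at least 4 and excludes symbols such as CG numbers. Some genes outside it lay further apart than those named, such as CG12506 (0.329 against 223 CPM) and beat-Ic (31.05 against 0.207 CPM). By the rule, the 5 lowest genes were scpr-A (2.39 against 3868 CPM), scpr-B (3.68 against 2215 CPM), scpr-C (7.43 against 3632 CPM), GstD5 (18.1 against 474 CPM) and the dynein light chain gene robl37BC (34.2 against 766 CPM). The 5 highest by the rule were Ccdc114, at 65.4 against 0.621 CPM, and 4 genes at or near the floor in WT. Of these, Spn38F was at 19.7 against 0.207 CPM and lectin-30A at 9.53 against 0.103 CPM. Mst57Dc was at 9.56 CPM and BG642167 at 7.26 CPM, each with 0 counts in WT, which allows up to 0.103 CPM. In all, 7333 of 13831 genes were at least 2-fold apart, 3775 higher and 3558 lower. With library size alone the split was 5665 higher and 2271 lower.

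**Figure D2:**
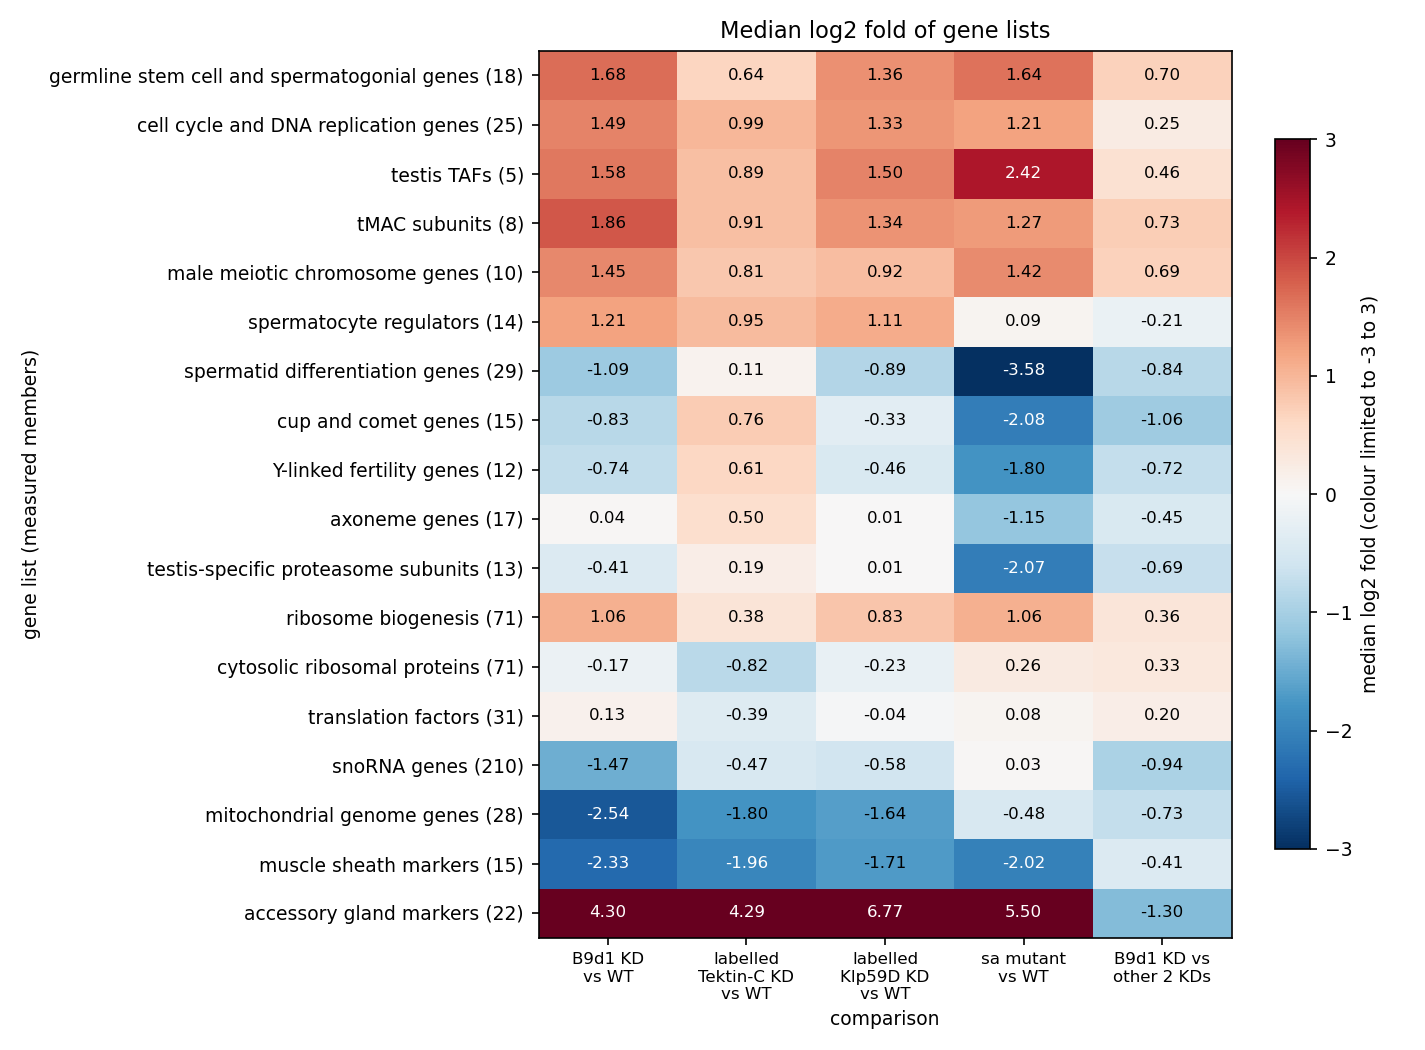
Median log2 fold of gene lists (measured members in parentheses) in 5 comparisons, each cell coloured by its median with the colour scale limited to -3 to 3, where red is higher in the first-named sample. Spermatid differentiation genes run from -3.58 in the sa mutant to 0.11 in the library labelled Tektin-C KD; with library size alone the sign turned for cytosolic ribosomal proteins in B9d1 KD and in the library labelled Klp59D KD against WT, for testis-specific proteasome subunits in B9d1 KD, for cup and comet genes, Y-linked genes and translation factors in the library labelled Klp59D KD, for mitochondrial genes in the sa mutant, and for spermatocyte regulators in B9d1 KD against the other knockdowns.

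The library labelled Tektin-C KD, in which Klp59D and not Tektin-C was low, was the nearest to WT by this count. Here 5292 genes (38.3%) were at least 2-fold apart from WT, 2932 higher and 2360 lower. The split turned to 2249 higher and 2459 lower when only the compared libraries were fitted and an adjusted p was also required. Spermatid differentiation genes had a median of 0.11 (percentile 25.9), with 4 of 29 at least 2-fold higher and 4 lower. Among them fzo, the mitofusin of the spermatid mitochondrial derivative, was at 733 against 122 CPM, Mst77F, a sperm chromatin protein gene, at 4050 against 3646 CPM, and Mst84Db at 1798 against 8374 CPM. The cup and comet genes were higher in 5 of 15 and lower in none (median 0.76, percentile 97.7), as seen for r-cup (409 against 97.4 CPM) and wa-cup (774 against 253 CPM). Y-linked fertility genes were higher in 4 of 12 (median 0.61). Among them the phosphatase gene Pp1-Y1 was at 32.7 CPM with 0 counts in WT, which allows up to 0.103 CPM.

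Cell cycle and DNA replication genes were higher in 11 of 25 (median 0.99, above all random lists), with polo kinase at 686 against 139 CPM. Centriole and basal body genes were higher in 8 of 15 (median 1.05, percentile 99.99) and spermatocyte regulators in 6 of 14 (median 0.95). Of the tMAC subunits 4 of 8 were higher (median 0.91), with comr at 37.5 CPM. Cytosolic ribosomal proteins were lower in 27 of 71 and higher in none (median -0.82, below all random lists), including RpL8 at 137 against 461 CPM and RpS23 at 621 against 1448 CPM. Translation factors had a median of -0.39 (percentile 0.16), and the elongation factor gene eEF2 was 1.75-fold lower. Heat shock proteins had a median of -0.56 (percentile 2.08), with 4 of 15 lower and 1 higher. Ribosome biogenesis genes were higher in 15 of 71 and lower in 1 (median 0.38, percentile 98.7). The accessory gland markers were higher in 21 of 22 (median 4.29), the muscle markers lower in 12 of 15 (median -1.96), and the mitochondrial genome gave 2.20% and 2.23% of counts. snoRNAs were lower in 71 of 210 and higher in 22 (median -0.47). The lowest genes by the naming rule were scpr-A, scpr-C and scpr-B, then AttC, an antimicrobial peptide gene, at 2.94 against 67.3 CPM and Erasp at 21.4-fold below WT.

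In the library labelled Klp59D KD, in which Tektin-C was low, 6475 genes (46.8%) were at least 2-fold apart from WT, 3271 higher and 3204 lower. Testis TAFs were higher in 4 of 5, tMAC subunits in 6 of 8 (median 1.34), germline stem cell and spermatogonial genes in 13 of 18 (median 1.36) and cell cycle genes in 17 of 25 (median 1.33), with none lower in any of the 4 lists. RnrS was at 87.9 against 5.45 CPM and spn-E at 107 against 25.1 CPM. Spermatid differentiation genes were lower in 12 of 29 and higher in 1 (median -0.89, percentile 0.16), with Mst84Db at 553 CPM and S-Lap7 at 2670 against 9088 CPM. Cup and comet genes (median -0.33) and Y-linked genes (median -0.46) lay inside the range of random lists and stood at 0.22 and 0.09 with library size alone. Ribosome biogenesis genes were higher in 30 of 71 and lower in 2 (median 0.83, above all random lists), and cytosolic ribosomal proteins were lower in 11 of 71 and higher in 1 (median -0.23, or 0.32 with library size alone). Accessory gland markers were higher in all 22 (median 6.77), with Acp36DE at 1952 CPM, and muscle markers lower in 13 of 15 (median -1.71). The mitochondrial genome gave 2.74% and 2.76% of counts. With library size alone the split of all genes was 5187 higher and 2033 lower.

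The sa mutant was compared with WT as the known arrest of the mature spermatocyte. Here 7490 genes (54.2%) were at least 2-fold apart, 3657 higher and 3833 lower, and 1237 were at least 8-fold lower. Spermatid differentiation genes were lower in 28 of 29 and higher in none (median -3.58, below all random lists). Mst77F was at 162 against 3646 CPM (22.5-fold lower) and S-Lap7 at 530 against 9088 CPM. Cup and comet genes were lower in 12 of 15 (median -2.08, percentile 0.40), with w-cup at 36.6 CPM, 75.6-fold lower. Axoneme genes were lower in 11 of 17 and higher in 2 (median -1.15, percentile 3.92), with betaTub85D at 155 against 3726 CPM. Y-linked genes were lower in 9 of 12 and higher in 2 (median -1.80). The proteasome lists parted: testis-specific subunits were lower in 9 of 13 and higher in 1 (median -2.07, percentile 0.27), with Prosalpha4T1 24.3-fold lower, whereas ubiquitous subunits were higher in 10 of 30 and lower in none (median 0.66, percentile 99.99).

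Transcripts of earlier stages stood higher in the sa mutant as well. Germline stem cell and spermatogonial genes were higher in 11 of 18 (median 1.64, above all random lists), cell cycle genes in 15 of 25 with 1 lower (median 1.21), and male meiotic chromosome genes in 6 of 10 (median 1.42). Ribosome biogenesis genes were higher in 39 of 71 and lower in none (median 1.06), cytosolic ribosomal proteins had a median of 0.26 (above all random lists, of which 95% lay between -1.17 and -0.18), and snoRNAs a median of 0.03 (percentile 53.7). Of the 4 testis TAFs other than sa, Taf12L was 5.36-fold, nht 6.42-fold and can 5.47-fold higher, and mia was at 43.2 against 48.2 CPM. The small heat shock protein gene Hsp26 was at 1804 against 297 CPM. The lowest genes by the naming rule included Acyp (1.80 against 262 CPM) and Dic3 (1.82 against 241 CPM). Accessory gland markers were higher in 21 of 22 (median 5.50) and muscle markers lower in 13 of 15 (median -2.02), while the mitochondrial genome gave 7.53% and 7.57% of counts. With library size alone the split was 6153 higher and 2494 lower.

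**Figure D3:**
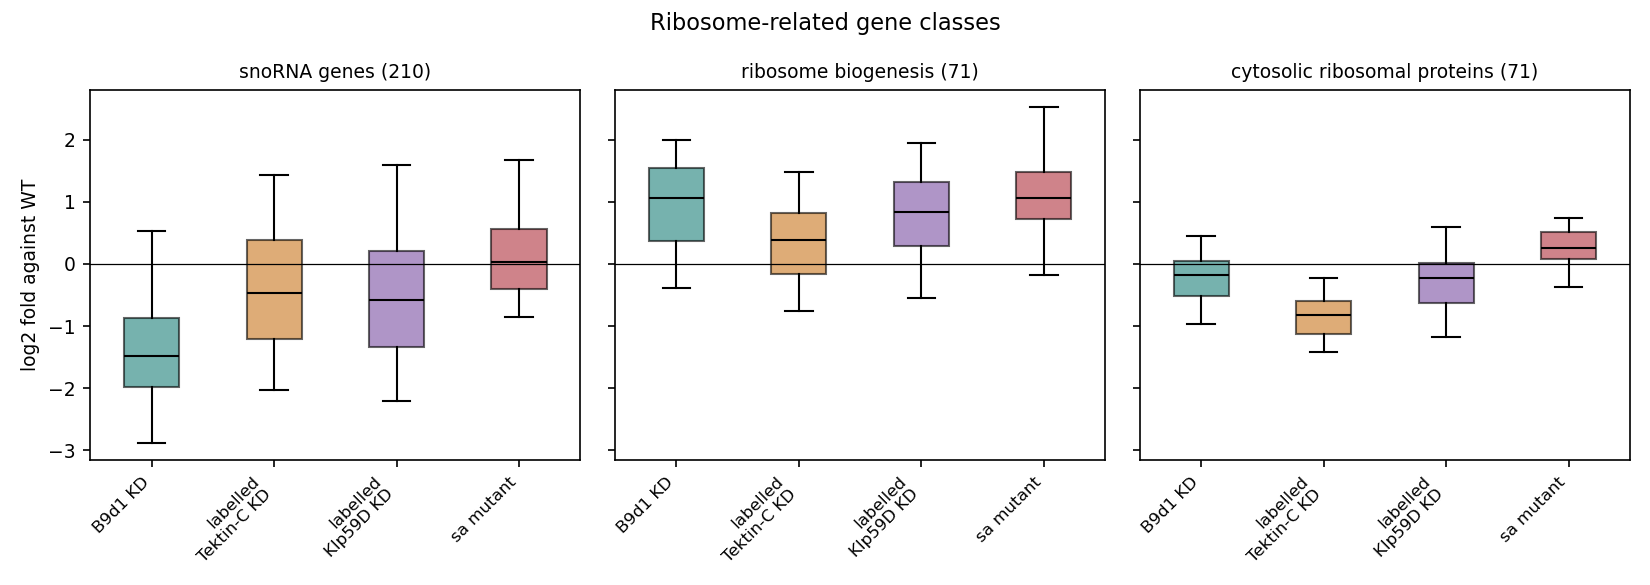
Log2 fold against WT of snoRNA genes (210), ribosome biogenesis genes (71) and cytosolic ribosomal protein genes (71) in each altered genotype, with the median (line), quartiles (box) and the 5th to 95th percentile (whiskers) over genes. The snoRNA median is -1.47 in B9d1 KD and 0.03 in the sa mutant, biogenesis medians lie between 0.38 and 1.06, and the ribosomal protein medians of B9d1 KD (-0.17) and of the library labelled Klp59D KD (-0.23) turn positive with library size alone.

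B9d1 KD was then compared with the mean of the other two knockdowns, which share its driver, temperature and days of growth but carry the mature spermatocyte label; this comparison bears on the series' interest in growth and ribosome biogenesis during meiotic prophase, and both libraries with the crossed targets enter it alike. List medians lay above 0 for early germ line genes and below 0 for late genes, with few members 2-fold apart in most lists. Germline stem cell and spermatogonial genes were higher in 4 of 18 (median 0.70, percentile 99.9), with nanos at 50.2 CPM against 10.1 in the library labelled Tektin-C KD and 22.1 in that labelled Klp59D KD. Among tMAC subunits (1 of 8 higher, median 0.73, percentile 99.5) wuc was at 204 CPM against 77.4 and 93.2. Male meiotic chromosome genes were higher in 2 of 10 (median 0.69, percentile 99.6). Cell cycle genes were higher in 6 of 25 and lower in none (median 0.25, percentile 88.3); the replication licensing gene dup was 3.66-fold and Mcm5 2.87-fold higher. Cup and comet genes were lower in 10 of 15 (median -1.06), spermatid differentiation genes in 5 of 29 (median -0.84), both below all random lists, and testis-specific proteasome subunits in 3 of 13 (median -0.69, percentile 0.45). For Y-linked genes the median was -0.72 (percentile 0.17), with 3 of 12 lower and 1 higher.

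The ribosome-related classes differed by smaller amounts, except for snoRNAs. Ribosome biogenesis genes were at least 2-fold higher in 8 of 71 and lower in none (median 0.36, percentile 99.8), with the nucleolar GTPase gene Non1 at 305 CPM against 119 in each reference and TAF1B, an RNA polymerase I factor, 2.90-fold higher. Cytosolic ribosomal proteins had a median of 0.33 with no gene 2-fold apart, above all random lists, and RpL3 was at 341 CPM against 141 and 208. Translation factors had a median of 0.20 (percentile 99.98). snoRNAs were at least 2-fold lower in 97 of 210 and higher in none (median -0.94, below all random lists), with snoRNA:Me28S-G764 at 74.2 CPM against 414 and 328. Mitochondrial genome genes were lower in 11 of 28 (median -0.73), accessory gland markers in 20 of 22 (median -1.30) and muscle markers in 1 of 15 (median -0.41).

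Among genes allowed by the naming rule, the largest rises in that comparison were Bili (56.4 CPM against 6.11 and 14.1), Lip2 (42.3 against 12.2 and 7.18), PolA1, the catalytic subunit of DNA polymerase alpha (79.1 against 11.3 and 27.6), vimar (74.0 against 12.8 and 26.7) and Rbm13 (86.5 against 18.2 and 26.9). Outside the rule, fne differed more (16.2 CPM against 0.776 and 0.728). Lowest by the rule, besides B9d1, scpr-A and scpr-B, were the sugar transporter gene Glut3 (5.64 against 103 and 43.6 CPM) and ORY (3.77 against 32.0 and 11.9 CPM). In all, 2869 genes (20.7%) were at least 2-fold apart, 1192 higher and 1677 lower, or 2120 higher and 1028 lower with library size alone. Against the mean of those 2 and the sa mutant, 2098 genes were, 1069 higher and 1029 lower. The 2 references were unequal: against the library labelled Tektin-C KD alone the count was 4752, and against that labelled Klp59D KD alone it was 1855. Spermatid differentiation genes had medians of -1.33 and -0.24 against these 2 references, germline stem cell genes 1.01 and 0.28, ribosome biogenesis genes 0.71 and 0.12, cytosolic ribosomal proteins 0.64 and -0.02, accessory gland markers -0.08 and -2.43, Y-linked genes -1.14 and -0.04, male meiotic chromosome genes 0.96 and 0.41, cup and comet genes -1.47 and -0.52, testis-specific proteasome subunits -1.20 and -0.30, tMAC subunits 0.96 and 0.48, cell cycle genes 0.69 and 0.18, translation factors 0.38 and 0.12, and snoRNAs -0.96 and -0.81. Of these lists, spermatid, germline stem cell, ribosome biogenesis, cytosolic ribosomal protein, Y-linked, male meiotic and cell cycle genes lay inside the range of random lists against the library labelled Klp59D KD (cell cycle genes also against the mean), and accessory gland markers against that labelled Tektin-C KD. When the 3 genotypes labelled mature spermatocyte were instead treated as replicates of that stage, edgeR's quasi-likelihood test called 0 genes at a Benjamini-Hochberg adjusted p under 0.05 (164 at an unadjusted p under 0.05), limma 0 (147 unadjusted) and DESeq2 6 (315 unadjusted). The young stage holds 1 sample in this fit, and 164 is below the 692 that chance alone would give at an unadjusted p under 0.05. The same edgeR fit with another genotype as the single sample also called 0 genes, with 745, 50 and 3563 unadjusted for the library labelled Tektin-C KD, that labelled Klp59D KD and the sa mutant. Fits of simulated data with this design recovered 22% of genes changed 16-fold and none changed 4-fold.

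Genes low in the sa mutant were examined in the same comparison, which uses neither the WT nor the sa mutant libraries that define them. They are called sa-dependent for short, but a need for sa was not tested, and they include 8 muscle sheath markers and 27 genes that were at least 16-fold higher in WT than in every other condition. The 2182 genes at least 4-fold lower in the sa mutant than in WT had a median of -0.78 in B9d1 KD against the other two knockdowns, where 95% of matched random lists lay between -0.13 and -0.05. Of these genes 802 were at least 2-fold lower and 32 higher. The median was -1.36 against the library labelled Tektin-C KD alone and -0.25 against that labelled Klp59D KD alone. The 1502 genes at least 4-fold higher in the sa mutant had a median of 0.36, with 300 at least 2-fold higher and 202 lower, and medians of 0.63 and 0.15 against the same 2 references.

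**Figure D4:**
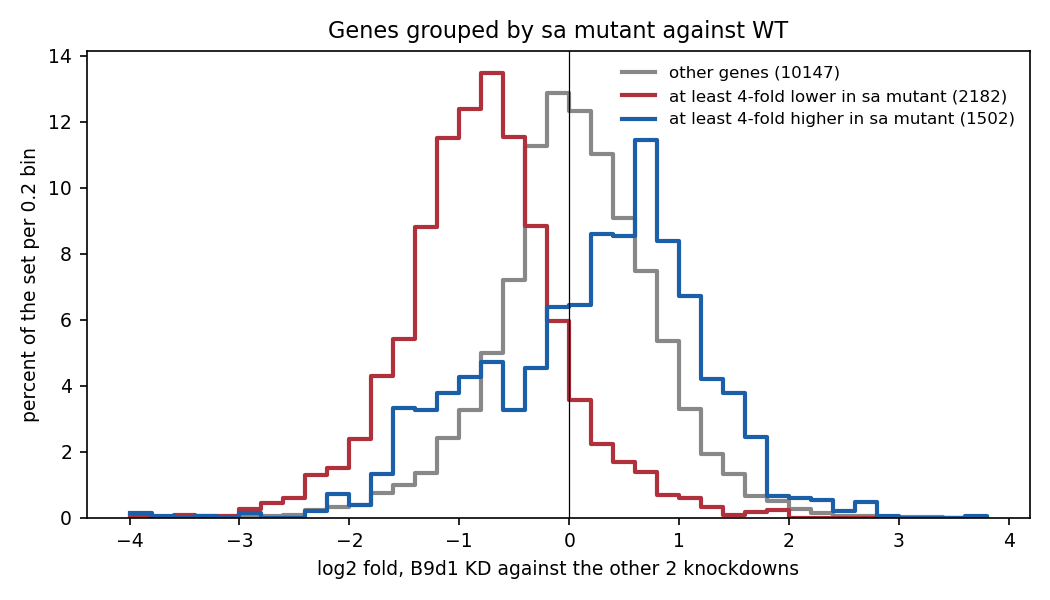
Distribution over genes of the log2 fold of B9d1 KD against the mean of the other 2 knockdowns (x axis), as the percent of each set per bin of 0.2 (y axis), for genes at least 4-fold lower (2182, red) or higher (1502, blue) in the sa mutant than in WT and for all other genes (10147, grey). The lower set is centred at -0.78 and the higher set at 0.36.

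Between the libraries labelled Tektin-C KD and Klp59D KD, 2937 genes (21.2%) were at least 2-fold apart, 2004 higher in the former and 933 lower, a split that became 1013 higher and 2587 lower with library size alone. Because the targeted transcripts went against these labels, the former is the library in which Klp59D was low (11.3-fold lower, fold 0.0885 [0.0838 to 0.0935]). The latter is the one in which Tektin-C was low (16.7-fold higher in the former [15.5 to 18.1]). Late genes stood higher in the library labelled Tektin-C KD: spermatid differentiation genes in 19 of 29 (median 1.15, above all random lists), Y-linked genes in 10 of 12 (median 1.33, percentile 99.99), testis-specific proteasome subunits in 7 of 13 (median 1.07, percentile 99.98) and cup and comet genes in 7 of 15 (median 0.79, percentile 99.3), with none lower. S-Lap7 was at 9263 against 2670 CPM, betaTub85D at 4154 against 1788 CPM and kl-5 at 154 against 50.5 CPM. The sa-dependent genes had a median of 1.10, with 1253 higher and 19 lower.

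Cytosolic ribosomal proteins (median -0.58, 2 of 71 lower) and ribosome biogenesis genes (median -0.51, 6 of 71 lower and 1 higher) lay below all random lists in the same comparison, and germline stem cell genes were lower in 5 of 18 (median -0.62, percentile 0.020). Apart from Tektin-C, the highest genes by the naming rule were the arrestin gene Arr1 (46.2 against 6.99 CPM), the importin gene alphaKap4 (83.9 against 15.3 CPM), Acyp (76.6 against 14.0 CPM) and the prefoldin subunit gene Pfdn6 (215 against 43.3 CPM). Apart from Klp59D, the lowest by this rule were msopa, Acp76A, Mst57Db and Acp53C14a, the last 3 of them seminal fluid genes, and 21 of 22 accessory gland markers were lower (median -2.36). Hemocyte markers were higher in 4 of 8 (median 0.82, percentile 98.9).

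B9d1 KD was finally compared with the sa mutant, to set the young against the mature arrest. Temperature, days of growth, driver, extra Dicer-2, the B9d1 knockdown and the loss of sa itself differ along with the stage label. These cannot be told apart here. Of 13831 genes, 5541 (40.1%) were at least 2-fold apart, 3312 higher in B9d1 KD and 2229 lower, or 2841 and 2891 with library size alone. Spermatid differentiation genes were higher in 27 of 29 (median 1.98), cup and comet genes in 12 of 15 (median 1.60), axoneme genes in 12 of 17 with 1 lower (median 1.58) and testis-specific proteasome subunits in 8 of 13 (median 1.33), with percentiles of 100 for the first and 99.7, 99.9 and 99.6 for the others. Mst77F and w-cup in B9d1 KD stood between WT and the sa mutant: Mst77F was at 3646, 1177 and 162 CPM in WT, B9d1 KD and the sa mutant, and w-cup at 2772, 506 and 36.6 CPM.

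Ubiquitous proteasome subunits (median -0.47, 4 of 30 lower) and cytosolic ribosomal proteins (median -0.49, 2 of 71 lower) lay below all random lists in this comparison. Ribosome biogenesis genes had a median of -0.25 (percentile 4.13), with 12 of 71 lower and 6 higher, and snoRNAs a median of -1.47, with 172 of 210 lower and 1 higher. Besides sa, the highest genes by the naming rule were Ptth, which encodes a brain neuropeptide hormone (48.2 CPM in B9d1 KD), Mst36Fa (78.5 against 1.92 CPM), the testis gamma-tubulin complex gene t-Grip91 (325 against 8.30 CPM) and the axonemal gene lobo (90.1 against 2.60 CPM). Besides B9d1, the lowest by this rule were AttC (3.15 against 31.8 CPM), the fly cuticular hydrocarbon enzyme gene Cyp4g1 (10.5 against 98.6 CPM), bero and Mst57Db. Hemocyte markers were lower in 6 of 8 (median -1.21) and accessory gland markers in 18 of 22 (median -1.83). The mitochondrial genome genes were lower in 25 of 28 (median -1.98).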

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

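Of the tests in this part, both tests on the targeted transcripts were chosen only after the result was seen, and the 3 tests on snoRNAs were chosen before their results were seen.

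The cup and comet genes drew attention because their median lay above WT in the library labelled Tektin-C KD (0.76, percentile 97.7) and below it in B9d1 KD (-0.83, percentile 2.27). The medians differ by 1.59 on the log2 scale, and this difference was not tested.

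Klp59D was low where the label says Tektin-C, and Tektin-C was low where it says Klp59D. The smaller of the 2 gaps to the lowest other condition was 4.96-fold, which is the observation that raised an exchange of the labels and so does not test it. Fewer late germ cells could lower other late genes along with the transcript. Without Tektin-C, the axoneme genes had a median of 0.57 against WT in the library with low Klp59D and 0.06 in the other. Spermatid differentiation genes had medians of 0.11 and -0.89 in the same 2 libraries, with 12 of 29 lower in the latter. RNA levels of these lists do not count cells, so they do not settle this explanation. An exchange of the labels, of the flies or of the files is a candidate explanation that stays open. A biological effect of either knockdown on the other gene would also need the named target to have escaped in both: Tektin-C was at 203 against 221 CPM in WT under its own label, and Klp59D at 335 against 340.3 CPM.

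The snoRNAs were lower in B9d1 KD than in the other two knockdowns by a median of -0.94 over 210 genes (quartiles -1.32 and -0.41), with -0.96 and -0.81 against each reference alone. A lower level of the genes that hold them is argued against, since 189 of the 210 lie in 62 host genes whose median was 0.44 (quartiles 0.08 and 0.75). Loss of short transcripts in library preparation cannot be told apart from an effect of B9d1. With sa-dependent and accessory gland genes left out, 287 protein-coding genes under 500 nt had a median of -0.30 with quartiles of -0.96 and 0.16. Their medians were -0.10 and -0.36 against the libraries labelled Tektin-C KD and Klp59D KD alone (0.43 against WT, where snoRNAs were at -1.47). With those genes kept, all 404 under 500 nt had a median of -0.57 against the mean of the other two knockdowns (quartiles -1.15 and -0.003). Of the 404, 129 were at least 2-fold lower and 17 higher. Loss of small structural RNAs in general also stays open, with a median of -0.29 over 28 small nuclear RNA genes and quartiles of -0.83 and 0.44 (-0.53 and -0.12 against each reference alone). A B9d1-dependent change in snoRNA processing or stability, or in the mix of cell stages, may add to this and was not tested.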

How the results depend on the processing

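In this part, each reference library alone and the sums in place of tests were chosen only after the result was seen. No list outside the range of random lists passed to the other side of their median under any scaling, filter or reference run, and no named gene at least 2-fold apart changed sign with RLE factors or library size alone, the 2 settings run for genes. Splits and list signs that turned with library size alone stand beside the results. Splits near even also turned elsewhere: B9d1 KD against WT to 3555 higher and 3580 lower with DESeq2, the library labelled Klp59D KD to 3189 and 3300 with RLE factors, 2227 and 2304 with CPM over 5, 3139 and 3224 with DESeq2 and 3205 and 3280 or 3222 and 3286 without its replicate 1 or 2 in turn, and the sa mutant to 4426 and 4121 with no filter and 3797 and 3771 without WT replicate 1. The number of genes at least 2-fold apart stayed within 1.5 times for all 7 comparisons except in 3 cases. B9d1 KD differed at 4752 genes from the library labelled Tektin-C KD alone and at 1855 from that labelled Klp59D KD alone, against 2869 from their mean. Between those 2 libraries the count was 1854 in place of 2937 with CPM over 5, a filter that leaves fewer genes (10563). For the 2 references the cause was not tested. The median of the sa-dependent genes lay between -0.84 and -0.63 under the other scalings and filters, and between -0.80 and -0.78 without each library in turn. Leaving out each library gave 7352 to 7396 genes for B9d1 KD against WT and 2859 to 2920 against the other two knockdowns. The replicate block, which pairs same-numbered libraries, gave 7272, 5176, 6420, 7430, 2902, 2938 and 5555 genes past both an adjusted p and 2-fold in the order of the report's comparisons (the 4 against WT first), and it moved no count by over 1.5 times. DESeq2 gave 7135, 5071, 6363, 7349, 2792, 2802 and 5367. Their p-values measure only the spread between libraries that were counted here as technical repeats. Of the list medians, 213 kept their place inside or outside the random range with RLE factors and 4 did not; with library size alone 214 did and 3 did not. With no filter 211 did and 6 did not, with CPM over 5 204 and 6, and without structural genes 200 and 3. In B9d1 KD against each reference alone, 28 did and 3 did not for the library labelled Tektin-C KD, and 23 did and 8 did not for that labelled Klp59D KD, where 6 lists moved inside the random range. Of the named gene values, 941 stayed on the same side of 2-fold with RLE factors and 14 did not, and 780 and 175 with library size alone. Not run were camera with a preset or estimated correlation, named-gene values under DESeq2 or the block, and the sa-dependent genes under DESeq2, the block or only the compared libraries. Depth limits genes near the floor, and most in WT, whose effective depth was lowest (29006081 counts).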

Other observations

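The 3 tests on genes far lower outside WT were chosen only after the result was seen, and the genes named in this part and the sets formed by fold were chosen after their values were seen.

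Among genes at 4 CPM or more in B9d1 KD, 21 stood at least 4-fold higher there than in every other condition. They included osk, which encodes the organizer of the germ plasm of the egg (25.9 CPM against 0.896 in WT, 0.902 and 2.48 in the libraries labelled Tektin-C KD and Klp59D KD and 1.01 in the sa mutant), fne, an RNA-binding protein gene of neurons (16.2 CPM, at most 0.776 elsewhere), Sse, the separase gene (15.6 CPM, at most 3.66 elsewhere), and the gustatory receptor gene Gr28b (9.15 CPM, at most 1.20 elsewhere). In the other direction, only genes at 4 CPM or more in every other condition were counted. Among these, B9d1 alone was at least 4-fold lower in B9d1 KD than in each other condition. The count of higher genes, again at 4 CPM or more in the condition itself, was 230 for WT, 18 and 5 for the libraries labelled Tektin-C KD and Klp59D KD, and 36 for the sa mutant.

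Heat shock protein genes were also uneven among the conditions. In B9d1 KD against the other two knockdowns their median was 0.42 (percentile 99.3), with 5 of 15 higher and 1 lower. In the sa mutant against WT the median was -0.58, inside the range of random lists, with 7 of 15 lower and 4 higher, the latter including Hsp26 and Hsp68. With library size alone this median turned positive. Hsp26 was at 1804 CPM in the sa mutant, which was kept at 22°C, and at 757, 323 and 379 CPM in B9d1 KD and the libraries labelled Tektin-C KD and Klp59D KD, which were moved to 30°C, against 297 in WT. Hsp68 was at 973 CPM in the sa mutant and at 683, 294 and 326 CPM in the same 3 knockdowns, against 398 in WT. Fat body markers had a median of 0.66 in B9d1 KD against the other two knockdowns (percentile 99.3), with 1 of 9 at least 2-fold higher, 1 lower and 7 within 2-fold.

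At 16 CPM or more in WT, 27 genes were at least 16-fold higher there than in every other condition, against 1 such gene for B9d1 KD and 0 for each other condition. Simulated counting noise gave 0 such genes and independent differences would give 0.00066, but neither holds the spread between samples, and all 4 folds share the WT sample, so the excess over them is not read as a shared effect. The most abundant were not absent elsewhere: scpr-A was at 2.39 to 29.4 CPM, scpr-B at 3.68 to 46.4 CPM and scpr-C at 7.43 to 34.9 CPM outside WT. The set also included Uro, the urate oxidase gene of excretory tubules (48.4 CPM in WT, at most 0.923 elsewhere), CG12506 (223 CPM, at most 2.54), CG42827 (336 CPM, at most 2.02) and lncRNA:Yu (256 CPM, at most 10.3). Among genes at 4 CPM or more in every condition other than WT, another 28 were at least 16-fold lower in WT than in each of them. Of these, 7 were in the accessory gland list, among them Acp36DE (14.4 CPM in WT, 341 to 1952 elsewhere) and Acp76A (0.241 CPM, 17.8 to 128 elsewhere). The others are outside that list, and whether they go with it was not tested. They include Mst57Da and Acp53C14b, both known as seminal fluid genes. Pp1-Y1 on the Y chromosome (0 counts in WT, which allows up to 0.103 CPM) and beat-Ic (0.207 CPM against 5.60 to 31.1) are among them too.

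Growth at 30°C is argued against as the only cause of this gap, because the sa mutant, which like WT stayed at 22°C, also showed it. In that mutant, 34 genes chosen in the same way on the 3 knockdowns alone had a median of -6.49 (quartiles -7.54 and -4.71). These 34 hold all 27 genes, and the other 7 were at -3.97 to -1.08 in the sa mutant, so 0 were within 2-fold of WT. The sa mutant has changes of its own, with 2182 genes at least 4-fold lower than in WT. Its values therefore cannot exclude a part of 30°C in the knockdowns. Loss of spermatids stays open. The spermatid list had a median of 0.11 in the library labelled Tektin-C KD while the 27 genes were at -6.70. Spermatocytes already switch on the spermatid program, so the level of this list need not follow the number of spermatids. Less muscle sheath or terminal epithelium would need a loss as large in their markers, whose lowest median was -2.33, with the abundant Mhc at 130 to 210 CPM against 673 in WT; the terminal epithelium list holds only 3 genes. A strain difference between WT and the other stocks, another tissue in the WT dissection, or part of the excess arising from the shared WT libraries may be the source, and none of them was tested.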
